A study of Mus musculus with 3 samples.

How the data were processed

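RNA of single cells was measured in 3 libraries of the anterior part of the palatal shelves of mouse embryos at embryonic day 13.5, on a C57BL/6J background. Per the labels' protocols, the shelves were dissected from cold heads and dissociated with trypsin, and libraries were made with the 10x Genomics Chromium 3′ chemistry, which counts unique molecular identifiers (UMIs) at the 3′ ends of transcripts. Groups were taken from the labelled genotype: 2 libraries labelled Kcnj2 KO/KO, both male, and 1 labelled KO/+, female. The series text says that embryos were run separately, so the spread behind the p-values comes from the 2 embryos labelled KO/KO. The text names the embryos with the targeted allele as KO/KO in one place and as KO/+ in another, while the labels give 2 KO/KO and 1 KO/+; the labels were used. The text states 7976, 6994 and 7268 cells for wild-type embryos (22238 in all), 7591 and 4067 cells for embryos it names KO/+ (11658 in all), and 100000 reads per cell. The deposited files held 8432, 5155 and 9894 barcodes for KO/KO 1, KO/KO 2 and KO/+, and no stated number equalled any of these or the numbers of cells kept here. No filter is stated with the cell numbers, so which barcodes it left is not known here.

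The deposited values were raw UMI counts per gene and barcode. The header of the matrices names Cell Ranger 6.0.1, while the submitters' processing notes name Cell Ranger 2.1.1, Seurat 4.0.4 and the genome build mm10. The role of Seurat is not given in the sources used here, and the whole-number counts were not normalized. The smallest UMI count of a deposited barcode was 500, 500 and 502. Genes were matched by Ensembl identifier to the GENCODE annotation of the same build, where 27722 of 27998 (99.0%) were found; 65 repeated symbols were told apart by identifier. The number of sample columns not used was 0.

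Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs passed, which left 8200, 4616 and 9490. Those under the gene minimum were 163, 503 and 341, and those over the mitochondrial limit 112, 201 and 143, some of them both. Scrublet, run per library, marked 0, 4 and 2 cells as doublets with its own threshold, so that threshold had not worked. The cells with the highest scores were removed instead, at 0.8% per 1000 cells (6.56%, 3.69% and 7.59%, or 538, 170 and 720 cells), a rate set after this was seen. This kept 7662, 4446 and 8770 cells with medians of 3068.5, 4255 and 3386 detected genes. Doublets below the removed scores stay among the cells. Cells of the 3 libraries were clustered together on 2000 variable genes without the sex lists, 30 principal components and 20 neighbours, with no integration. The Leiden resolution of 0.4 was chosen after 8 values from 0.02 to 2 were tried and the clusters seen, because at a value of 1 more clusters with mesenchyme markers would have stayed unnamed under the naming rule, among them clusters held mostly by 1 of the groups. At 0.4 cluster 9 alone did so, apart from the low-UMI cluster 14. The limits on genes and mitochondrial UMIs and the fold in the naming rule were also set after the files were looked at.

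Clusters were named from 14 marker classes fixed before the data were examined: mesenchyme, osteogenic, chondrogenic, epithelium, periderm, endothelium, pericyte, skeletal muscle, glia, neuron, macrophage, other leukocyte, erythroid and melanocyte. A name needed at least 3 markers, each detected in 25% of the cluster's cells and at least 3-fold above all other cells; a cluster without such a class but with 3 detected mesenchyme markers was called mesenchyme-like. A cluster stayed unnamed if its median UMI count was under its libraries' median divided by 3 with none of its markers among its top 10 genes, or if another class had more markers among these. By these rules cluster 14, with a median of 1860 UMIs, and cluster 9 stayed unnamed. Mesenchyme-like and osteogenic-like clusters were joined as mesenchymal cells. A class was tested if each library had at least 50 of its cells. Naming is a reconstruction, and shares may differ from the study's for that reason.

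UMI counts were summed per library and class and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with TMM scaling, the filterByExpr count filter and Benjamini-Hochberg adjustment at 0.05. The design had 1 residual degree of freedom, from the 2 libraries labelled KO/KO, and the library labelled KO/+ was assumed to vary like them. edgeR estimated infinite prior degrees of freedom for the mesenchymal, epithelial and interaction fits. In these the spread shared by genes of like level replaced each gene's own spread between embryos. Genotype and sex coincided, so no term for sex could be fitted. The difference of the genotype effect between epithelial and mesenchymal cells was tested as an interaction with the library as a block. Fold changes are log2 of KO/KO over KO/+ as labelled. Each SE is the absolute log2 fold change divided by the square root of edgeR's F statistic. It restates the test and is not a separate estimate of error, above all at very low counts. A gene at 0 in one group has its fold given against a floor of 3 counts, per library for KO/+ and over the group for KO/KO; with 1 to 3 counts the ratio has an exact counting interval. Intervals of counts are exact Poisson and those of shares exact binomial (Clopper-Pearson), at 95%, and cover counting error only. Shares of cells with a UMI and cell cycle phases were taken after thinning each cell to 5000 UMIs, leaving out shallower cells. Phases were scored with scanpy 1.11.5 from the S and G2/M lists, and free RNA can enter such calls.

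The 23 gene lists were fixed before the data were examined: activity-induced, heat shock, BMP, TGF-beta, hedgehog, WNT and FGF signalling, palate patterning, osteogenesis, chondrogenesis, extracellular matrix, potassium channels, calcium handling, sodium and chloride transport, S phase, G2/M, glycolysis and hypoxia, mitochondrially encoded, nuclear oxidative phosphorylation, ribosomal proteins, neighbours of Kcnj2 on chromosome 11, Y-linked, and X inactivation with escape. Lists with at least 5 measured members (22) were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over the lists, and again with the correlation estimated per list. A list's median was also set among 10000 random lists matched on mean expression. Members are counted as called after adjustment over all genes tested and over the list alone.

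Named genes followed a rule fixed before the data were examined. In mesenchymal cells these were the 12 higher and 12 lower genes with the smallest adjusted p among called genes whose CPM in both libraries labelled KO/KO lay on the same side of KO/+. Genes of the sex lists, pseudogenes, models without a standard symbol, haemoglobins and mitochondrially encoded genes were left out. Other tests named 5 per direction and each list up to 4 members with the smallest p. Kcnj2, Xist, the Y-linked list, Sox9 and called neighbours of Kcnj2 were always named. Some genes that this rule takes are not reported here. Members named beyond these, and called cell type markers, were chosen after their values were seen.

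Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE size factors, no count filter, all deposited barcodes, sums thinned to equal depth, each replicate left out, mesenchyme-like clusters alone, halved and doubled resolution (0.2 and 0.8), G1 cells only, equal cells per cluster, an estimated correlation, phases without thinning and CPM without TMM factors. Added after seeing the data were the mesenchymal class with cluster 9, clusters with at least 50 cells in each library (shared clusters), clustering without the called genes, the nearly absent clusters (those in which KO/+ gave under 1% of the mesenchymal cells) at other resolutions, and list medians with equal cells, in shared clusters and in G1 cells.

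Each edgeR test was run first on simulated counts drawn from the libraries' means, with 200 genes changed by 2-fold or 4-fold, or by 4-fold alone for the interaction. All simulated genes had the same spread between libraries, which meets edgeR's assumptions by construction. False calls in the real libraries may therefore be more than in the simulations. The camera, DESeq2 and limma-voom tests were not simulated. In the mesenchymal simulation (15916 genes) 15% of 2-fold and 90% of 4-fold changes were recovered, with 1 false call; in that of all cells (16870 genes) 11% and 77%, with 4; in that of epithelial cells (13210 genes) 17% and 84%, with 5; and in that of endothelial cells (10875 genes) 5% and 73%, with 2. The interaction simulation (14823 genes) recovered 40% of 4-fold changes, with 3 false calls. Most 2-fold changes are therefore below what these libraries can show. Other tools were scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and Python 3.11.15.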

Results

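Transcripts were counted in single cells of the anterior palatal shelves, the paired outgrowths that form the front of the secondary palate, taken from mouse embryos at embryonic day 13.5. The embryos carried a targeted allele of Kcnj2, which encodes the inwardly rectifying potassium channel Kir2.1. The study asked how loss of this channel changes gene expression in the palate, with attention to genes that electrical activity induces. The analysed set held 2 libraries labelled KO/KO, both from male embryos, and 1 library labelled KO/+, from a female embryo; wild-type libraries were not analysed here. Each library came from cells of 1 embryo run on its own. The deposited matrices held 84283694, 91776651 and 137678746 unique molecular identifiers (UMIs) in 8432, 5155 and 9894 barcodes for KO/KO 1, KO/KO 2 and KO/+. After filtering, 7662, 4446 and 8770 cells were kept, with medians of 8945, 18266.5 and 12497 UMIs per cell. Genotype and sex went together in these libraries, and the spread between replicates came from the 2 libraries labelled KO/KO alone.

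Kcnj2 transcript was more abundant in the libraries labelled KO/KO than in the library labelled KO/+, which is the direction opposite to that of a lost transcript. The gene lies on chromosome 11 of mm10, from 111066164 to 111076821. In summed mesenchymal cells its level was 44.7 ± 0.27 CPM (counts scaled to a common library total; mean ± SD, n = 2) in the libraries labelled KO/KO and 18.6 CPM in the library labelled KO/+, from 2880, 3191 and 1495 UMIs. The difference was 1.26 on the log2 scale (SE 0.28, edgeR adjusted p = 0.0004). Without scaling by the trimmed mean of M-values (TMM) the levels were 46.5 ± 3.50 and 17.2 CPM. Each of the 6 mesenchymal clusters that had enough cells in every library showed the same order. In epithelial cells the levels were 14.3 ± 2.94 and 9.54 CPM and did not pass the test (log2 difference 0.60, SE 0.32, edgeR adjusted p = 0.846). Endothelial cells held 40.8 and 19.2 CPM in KO/KO 1 and KO/KO 2 and 11.7 CPM in KO/+ (log2 difference 1.33, SE 0.40, edgeR adjusted p = 0.114), and all cells together 39.6 ± 1.27 and 16.0 CPM (log2 difference 1.31, SE 0.26, edgeR adjusted p = 0.0758). In all cells the call was made by DESeq2, with other size factors, at equal depth and over all deposited barcodes (adjusted p from 0.000501 to 0.0120 in these, and from 0.000501 to 0.747 over all alternatives), while in mesenchymal cells it was lost over all deposited barcodes (log2 difference 1.31, edgeR adjusted p = 0.299, range over 13 alternatives 4.5e-05 to 0.299).

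In mesenchymal cells thinned to 5000 UMIs, 18.1% and 17.8% of cells in the libraries labelled KO/KO and 7.02% in the library labelled KO/+ held a Kcnj2 UMI, against 28.0%, 42.5% and 17.0% without thinning. Thinned erythroid cells, a class outside the palatal tissue, held one in 4.17%, 3.45% and 2.97% of 24, 29 and 101 cells. Median depths were 8769.5, 18419 and 12425 UMIs in mesenchymal cells and 15214, 30553 and 4971 UMIs in erythroid cells. The labels do not say which part of the gene the targeted allele lacks, and UMIs from the end of a transcript outside a deleted part check nothing about the protein. For this reason the groups are named below by their labels, and every direction is one between libraries so labelled.

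**Figure D1:**
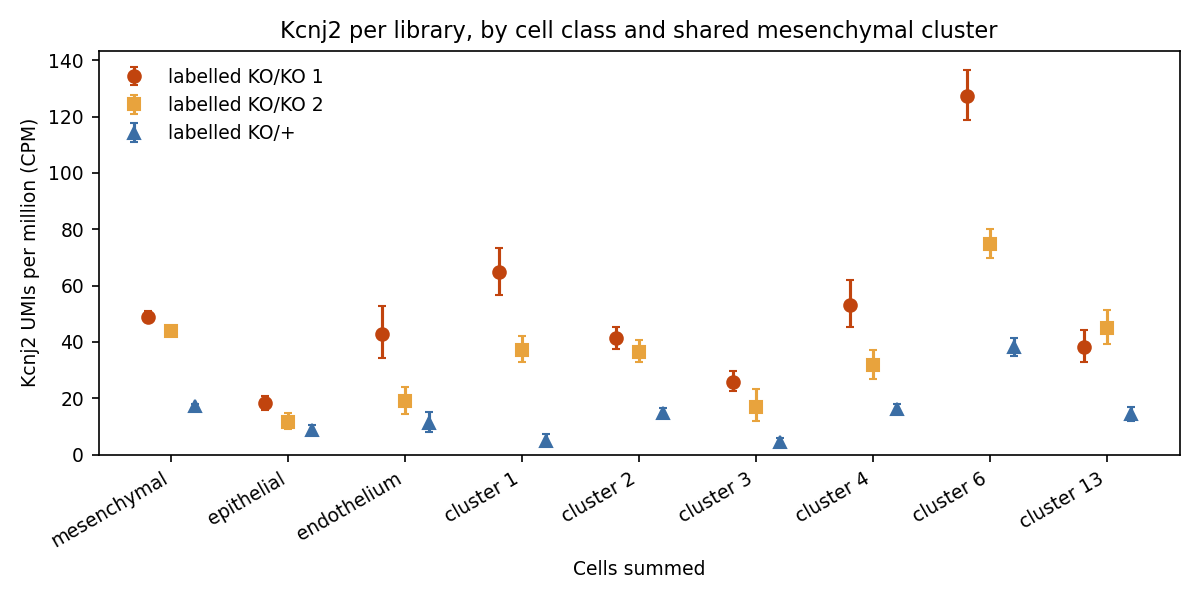
Kcnj2 level (vertical axis, CPM without TMM scaling) in each library for the summed cells of a class or of a shared mesenchymal cluster (horizontal axis), with exact Poisson 95% intervals that cover counting error only. In mesenchymal cells and in all 6 shared clusters both libraries labelled KO/KO lay above the library labelled KO/+.

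Sex-linked transcripts followed the sexes given in the labels. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together had 14999 and 14696 UMIs in KO/KO 1 and KO/KO 2 and 0 in KO/+. Xist, the RNA that coats the inactive X chromosome, had 16, 6 and 146956 UMIs. In mesenchymal cells 4 of 4 Y-linked genes were called higher in the libraries labelled KO/KO, also when adjusted over the list alone, and Ddx3y was at least 1995-fold higher against a floor of 3 counts in the library labelled KO/+. Of 7 measured genes of the list on X inactivation and escape from it, Xist and Pbdc1 were called lower (log2 −14.21 and −0.96), with 2 lower when adjusted over the list alone; the Pbdc1 call was lost with equal cells per cluster (edgeR adjusted p = 0.0694, range 0.00852 to 0.429). The list passed the set test (adjusted p = 0.000936), and adjusted p = 0.572 with an estimated correlation.

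Of 33 measured neighbours of Kcnj2 on chromosome 11, a total of 3 were called higher in mesenchymal cells of the libraries labelled KO/KO. These were Prkca, a protein kinase C gene (log2 1.43, SE 0.29), Fam20a (1.53, SE 0.41) and Axin2, a feedback inhibitor of WNT signalling (0.89, SE 0.28). The count was 3 when adjusted over the list alone, and DESeq2 called 1. The 3 calls were lost with equal cells per cluster (edgeR adjusted p = 0.120 for Prkca, 0.183 for Fam20a and 0.182 for Axin2, with highest values over the alternatives of 0.320, 0.550 and 0.646), and without KO/KO 1 Axin2 stood at 0.53. Sox9, the chondrogenic regulator that shares this region, had 113 ± 17.5 CPM (SD, n = 2) and 94.1 CPM and was not called (log2 0.26, SE 0.29, edgeR adjusted p = 0.779). The set test gave an adjusted p of 0.0414 for the neighbours, and adjusted p = 0.572 with an estimated correlation.

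Clustering gave 17 clusters, of which 9 formed the mesenchymal class. Mesenchyme-like and osteogenic-like clusters made up 84.9 ± 2.05% of cells (SD, n = 2) in the libraries labelled KO/KO and 74.0% in the library labelled KO/+ (exact binomial 95% interval 73.0 to 74.9). That order turned at doubled clustering resolution (a difference of −0.721 percentage points) and over all deposited barcodes (−13.6), where more clusters stayed unnamed. Epithelial cells, from epithelium-like clusters, made up 11.7% and 4.34% in the libraries labelled KO/KO and 10.2% (9.61 to 10.9) in the library labelled KO/+. At doubled resolution they made up 4.06 ± 2.34% against 2.96%, which turned the order of the means. There a cluster of 437, 76 and 588 cells, with Epcam in 97.6% of them, stayed unnamed and was left out of the class. Endothelium-like cells made up 1.16 ± 0.0493% and 0.981%, macrophage-like cells 0.708 ± 0.0145% and 0.639%, and glia-like cells 0.433 ± 0.0711% and 0.582%, with exact intervals in the library labelled KO/+ of 0.785 to 1.21, 0.483 to 0.828 and 0.433 to 0.764%. The order of the endothelium-like share turned at doubled resolution too (1.20 ± 0.0877% against 1.30%). Erythroid-like cells made up 0.502 ± 0.212% in the libraries labelled KO/KO and 2.31% (2.01 to 2.65) in the library labelled KO/+. Unnamed clusters held 4.34 ± 2.96% and 11.3% (10.6 to 11.9), among them cluster 9 with 19, 8 and 369 cells, which had mesenchyme markers and the pericyte marker Rgs5 among its leading genes. These shares were not tested. The 3 libraries split 2 against 1 in 3 ways, so that an exact permutation test could not go below p = 0.333.

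A part of the mesenchyme of the libraries labelled KO/KO had almost no counterpart in the library labelled KO/+. Mesenchymal cells clustered without the genes called between the groups, on 1646 of 2000 variable genes, formed 10 clusters. In 1 of them lay 20.5% and 28.1% of mesenchymal cells of the libraries labelled KO/KO and 0.123% of those of the library labelled KO/+, that is 1311, 1079 and 8 cells (exact binomial 95% interval in the latter 0.0532 to 0.243%). In the clustering of all cells, cluster 0 (1691, 1211 and 9 cells) and the osteogenic-like cluster 7 (573, 452 and 5 cells) together held 39.4 ± 5.59% (SD, n = 2) and 0.216% (0.118 to 0.362). At halved resolution no cluster was nearly absent from the library labelled KO/+ (0%), so the separation held at the finer resolutions only. The clustering without the called genes kept genes that differed without being called, and no integration was used. At doubled resolution a cluster of 726, 765 and 1 cells, and over all deposited barcodes one of 1450, 1166 and 4, stayed unnamed, because a pericyte marker, Kcnj8, stood among their leading genes. In the other direction, cluster 9 (19, 8 and 369 cells, outside the class) and at doubled resolution a mesenchyme-like cluster of 31, 5 and 638 cells lay mostly in the library labelled KO/+. The latter was led by genes named below as lower, among them Scx, Dlk1, Angptl1 and Peg10. Without the called genes, the cluster with the highest share of its cells from the library labelled KO/+ held 334, 114 and 858. Because clusters 0 and 7 held so much of the class in one group, the mesenchymal values below compare unlike mixtures of clusters, and calls of named genes that were lost with equal cells per cluster are given as lost. Among named genes that kept their call there, the log2 value moved by over 1.5 times for Gria2 (from 4.21 to 2.12), Cthrc1 (2.39 to 1.32), Dkk2 (3.87 to 2.56), Bmp2 (2.27 to 1.47), Sp7 (3.77 to 2.47), Ibsp (6.77 to 4.37) and Stmn2 (2.91 to 1.80).

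In mesenchymal cells, members of the lists of osteogenesis, extracellular matrix, WNT signalling and BMP signalling genes stood among those with higher levels in the libraries labelled KO/KO. Smpd3, a neutral sphingomyelinase needed for bone mineralisation, had 65.2 ± 5.34 CPM (SD, n = 2) against 1.25 CPM (log2 5.71, SE 0.38). Col12a1, a collagen of dense connective tissue, had 138 ± 1.08 against 9.08 CPM (log2 3.93, SE 0.35), and Tnn, the matrix protein tenascin-W, 35.0 ± 4.16 against 1.88 CPM (log2 4.22, SE 0.34). Dkk2, a secreted modulator of WNT signalling, had 70.7 ± 17.6 against 4.85 CPM (log2 3.87, SE 0.34). Among the genes with lower levels were Scx, a transcription factor of tendon progenitors (12.9 ± 2.94 against 41.5 CPM, log2 −1.68, SE 0.26), and the imprinted genes Peg10 (88.9 ± 43.7 against 270.5 CPM, log2 −1.61, SE 0.29) and Dlk1 (48.1 ± 17.7 against 136 CPM, log2 −1.50, SE 0.27).

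The other named genes with higher levels were Tmsb15b1 (log2 5.04), Pde10a, a cyclic nucleotide phosphodiesterase (4.29), Spock1, a matrix proteoglycan (4.28), Gria2, a glutamate receptor subunit (4.21), Ptgfr, the prostaglandin F receptor (4.09), Gfra2, a receptor for neurturin (3.56), and C1qtnf3 (5.24). Trim12a had 1 UMI in the library labelled KO/+, for a ratio of 795 with a counting interval from 142 to 31418. Tmsb15b1 and Trim12a have near-identical relatives, so reads could be shared and their values are uncertain. Named genes with lower levels also included Fbxo44 (log2 −3.60), Ren1, the renin gene (−3.13), Cdh15, a cadherin of muscle cells (−2.59), Pcp2 (−2.17), Angptl1 (−1.58), Cited1 (−1.57) and Fam212a (−1.49). Tsix (−11.55) lies antisense to Xist, and Erdr1 (−1.87) in the region shared by the X and Y chromosomes, so both are uncertain. Ren1 is uncertain too, since some mouse strains carry a near-identical copy. Without KO/KO 1, Cdh15 stood at log2 −4.50 and Angptl1 at −2.73, or at −0.95 without KO/KO 2, and DESeq2 called neither (adjusted p = 0.717 and 0.805, lowest over the alternatives 1.4e-08 and 3.9e-09).

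**Figure D2:**
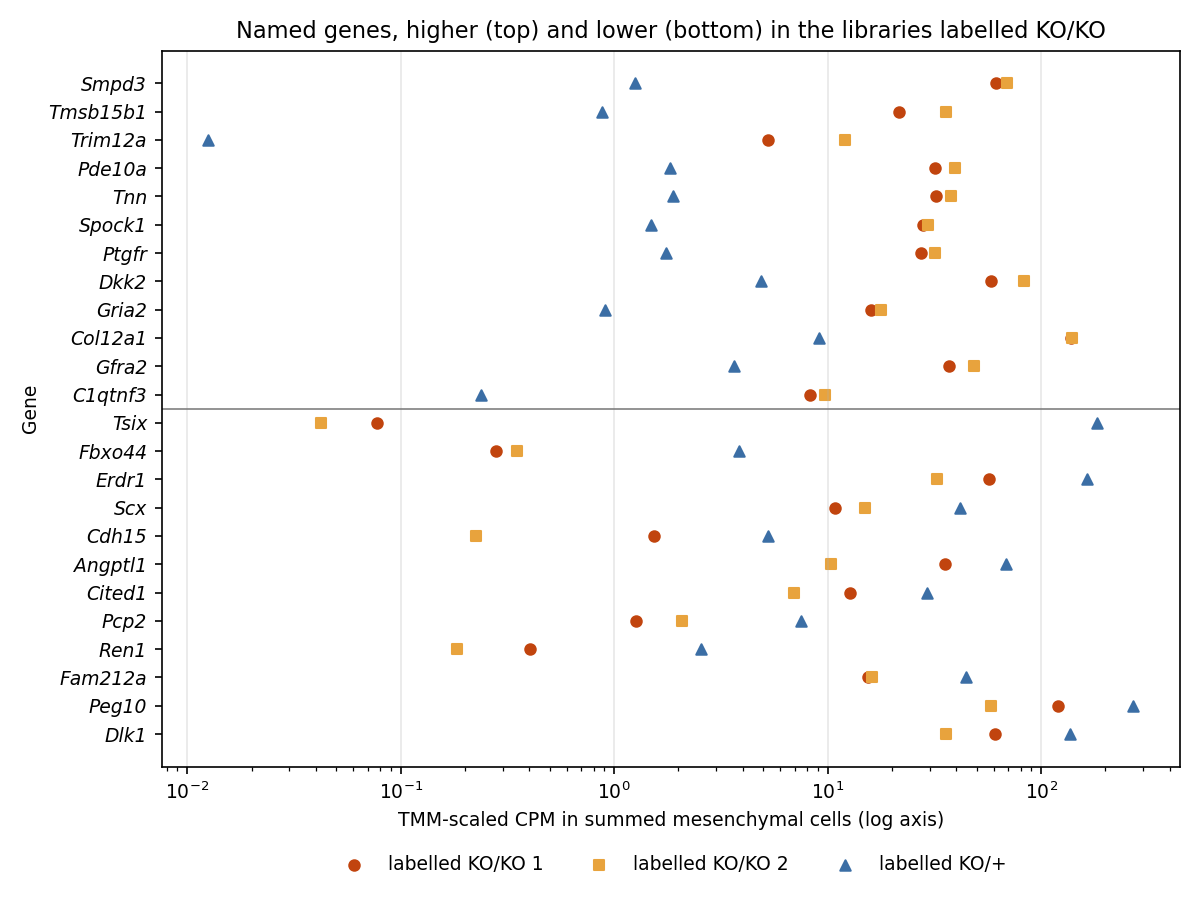
TMM-scaled CPM (horizontal, log axis) of the 24 genes named by the smallest adjusted p, one point per library, in summed mesenchymal cells. Higher genes stand above the line and lower genes below it, and in each of them both libraries labelled KO/KO lie on the same side of the library labelled KO/+.

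In this comparison edgeR's quasi-likelihood test called 844 of 15916 genes, 645 higher and 199 lower in the libraries labelled KO/KO. The count was 487 with DESeq2, 340 with equal cells per cluster, 374 in the clusters shared by the libraries, and 6 over all deposited barcodes, where Tsix was the sole named gene outside the sex lists to keep its call. A total of 246 genes, 213 higher and 33 lower, were called in the first test and under DESeq2, limma-voom, RLE size factors, equal depth, equal cells per cluster and shared clusters alike.

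Of 37 measured genes induced by electrical activity and other acute stimuli, 17 were called higher and 0 lower in mesenchymal cells of the libraries labelled KO/KO. With equal cells per cluster the count was 13. Adjusted over the list alone, 25 were higher and 1 lower, and DESeq2 called 7. Nr4a1, a nuclear receptor, had 125.5 and 45.1 CPM in KO/KO 1 and KO/KO 2 against 7.86 CPM (log2 3.44, SE 0.33), though DESeq2 did not call it (adjusted p = 0.0890, range over 13 alternatives 2.5e-22 to 0.376). The AP-1 members Fosl2 (26.4 and 19.3 against 3.28 CPM, log2 2.80) and Junb (190 and 95.9 against 33.1 CPM, log2 2.11) and the zinc finger factor Egr2 (18.4 and 7.20 against 2.50 CPM, log2 2.35, and 1.52 without KO/KO 1) were called too. The list's median was 0.94 on the log2 scale, 0.49 without KO/KO 1 and 1.35 without KO/KO 2, and it passed the set test (adjusted p = 1.7e-07; adjusted p = 0.572 with an estimated correlation). In thinned mesenchymal cells 39.9% and 16.7% of cells of KO/KO 1 and KO/KO 2 and 3.31% of KO/+ held an Nr4a1 UMI, against 12.1%, 3.89% and 3.91% of epithelial cells, whose median depths were 11595, 24128 and 17572.5 UMIs; without thinning the mesenchymal shares were 52.3%, 38.4% and 8.35%. Heat-shock genes had 0 of 14 members called by edgeR, DESeq2 and limma-voom, with 0, 1 and 0 at an unadjusted p under 0.05, 0 by edgeR adjusted over the list alone, and a median of −0.27 (adjusted p = 0.0989; adjusted p = 0.572 with an estimated correlation).

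Among BMP signalling genes 6 of 29 were higher in mesenchymal cells of the libraries labelled KO/KO, or 17 adjusted over the list alone, and none was lower. They included the antagonist Nog (log2 3.83, SE 0.44) and the ligands Bmp2 (2.27, SE 0.30), Bmp3 (2.17, SE 0.32) and Bmp5 (2.03, SE 0.35). WNT signalling genes had 12 higher and 1 lower of 35, or 14 and 2 adjusted over the list alone, and DESeq2 called 7; with equal cells per cluster 2 of 32 measured were called, both higher. Beside Dkk2 these were led by the nuclear effector Lef1 (2.60, SE 0.31), the secreted inhibitor Notum (4.11, SE 0.80) and the receptor Lgr5 (1.56, SE 0.30), while Rspo3, a WNT potentiator, was lower (−1.43). The calls of Lgr5, Notum and Rspo3 were lost with equal cells per cluster (edgeR adjusted p = 0.0993, 0.0543 and 0.207, ranges over 13 alternatives 2.5e-09 to 0.630, 5.3e-06 to 0.312 and 2.7e-06 to 0.318). Both lists passed the set test (adjusted p = 5.4e-06 for BMP and 3.6e-05 for WNT signalling), with adjusted p = 0.572 for each with an estimated correlation.

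FGF signalling genes had 5 higher and 1 lower of 19 in mesenchymal cells, or 6 and 2 adjusted over the list alone. The receptors Fgfr3 (log2 2.81) and Fgfr2 (1.22) and the ligands Fgf7 (2.03) and Fgf2 (1.20) were higher in the libraries labelled KO/KO, and Etv4, a target of the pathway, was lower (−0.90). The Etv4 call was lost with equal cells per cluster (log2 −0.49, edgeR adjusted p = 0.500) and was kept under 2 of the 13 alternatives with a test (range 0.0205 to 0.652). TGF-beta signalling had 2 higher of 19, Ctgf (2.07) and Skil (0.94), or 4 adjusted over the list alone; Skil was lost with equal cells per cluster (edgeR adjusted p = 0.0981, range 0.0131 to 0.597). Hedgehog signalling had 1 higher of 18, the co-receptor Boc (0.98), or 3 higher and 1 lower adjusted over the list alone, and Boc was lost with equal cells per cluster (edgeR adjusted p = 0.123, range 0.00308 to 0.478). The hedgehog median was −0.03, or 0.05 without KO/KO 2, and the mean 0.15. limma's camera test of the lists gave adjusted p = 0.0433 for FGF, 0.00927 for TGF-beta and 0.992 for hedgehog signalling. With an estimated correlation these were adjusted p = 0.572, 0.572 and 0.993.

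Osteogenesis genes had 8 higher and 0 lower of 17 in mesenchymal cells of the libraries labelled KO/KO, or 10 higher and 1 lower adjusted over the list alone. Sp7, the osteoblast transcription factor osterix, had 13.9 and 25.3 CPM against 1.43 CPM (log2 3.77, SE 0.35). Cthrc1, a secreted protein of matrix remodelling (2.39), and Dlx3 (4.47) were called too, and Ibsp, bone sialoprotein, had 1 UMI in the library labelled KO/+ for a ratio of 140 with a counting interval from 24.9 to 5572. In thinned cells 5.93% and 9.49% of mesenchymal cells of KO/KO 1 and KO/KO 2 and 0.645% of those of KO/+ held an Sp7 UMI, and 9.50%, 21.7% and 1.66% without thinning; in thinned epithelial cells 1 of 829, 0 of 180 and 0 of 845 did. The list's median was 1.24 (set test adjusted p = 1.0e-05; adjusted p = 0.572 with an estimated correlation). Of 12 chondrogenesis genes Matn4 alone was called higher (log2 3.14), also adjusted over the list alone, and its call was lost with equal cells per cluster (edgeR adjusted p = 0.116, range 3.0e-14 to 0.273); the list did not pass (adjusted p = 0.131; adjusted p = 0.572 with an estimated correlation). Among cell type markers, 4 of 8 osteogenic markers and 3 of 7 pericyte markers were higher in the same cells, the latter being Kcnj8, Abcc9 and Ndufa4l2. The Ndufa4l2 call was lost with equal cells per cluster (edgeR adjusted p = 0.376, range 2.2e-07 to 0.550).

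Extracellular matrix genes had 13 higher and 0 lower of 37 in mesenchymal cells of the libraries labelled KO/KO, or 15 higher and 1 lower adjusted over the list alone. Besides Col12a1 they included the proteoglycan Dcn (log2 1.88, SE 0.30) and the collagens Col6a3 (1.91, SE 0.30) and Col14a1 (1.48, SE 0.30). The set test gave adjusted p = 1.8e-06, and adjusted p = 0.572 with an estimated correlation.

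Potassium channel genes had 5 higher and 0 lower of 32 in these cells, and 5 adjusted over the list alone. Apart from Kcnj2 they were Kcnj8 (log2 4.05, SE 0.40) and Abcc9 (2.42, SE 0.45), the pore and regulatory subunits of an ATP-sensitive channel, Kcne4 (2.94, SE 0.53) and Kcna1 (2.54, SE 0.49). Calcium handling genes had 7 higher of 52, or 9 adjusted over the list alone, or 3 of 50 with equal cells per cluster, among them Nfatc2 (2.42) and Mef2c (1.78), both transcription factors that respond to calcium, and the channel subunit Cacna2d2 (2.02). The Cacna2d2 call was lost with equal cells per cluster (edgeR adjusted p = 0.164, range 6.0e-06 to 0.444). Ryr3, a calcium release channel, had 3 UMIs in the library labelled KO/+, for a ratio of 24.1 with a counting interval from 8.02 to 118. Of 21 genes of sodium and chloride transport Atp1b2 alone was called (1.29), with 0 adjusted over the list alone, and its call was lost under each of the 13 alternatives with a test (adjusted p from 0.0507 to 0.556). The set test gave adjusted p = 0.00232 for potassium channels, 0.000359 for calcium handling and 0.0211 for sodium and chloride transport, each with adjusted p = 0.572 with an estimated correlation.

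Palate patterning genes went both ways. Of 35 measured, 4 were higher and 3 lower in mesenchymal cells of the libraries labelled KO/KO, and the same numbers held adjusted over the list alone, while DESeq2 called 4 in all. The homeobox genes Meox1 (3.63 ± 0.33 against 0.424 CPM), Dlx6 (1.49) and Dlx1 (0.87) and the zinc finger gene Osr1 (1.11) were higher, and Meox2 (−1.45), Osr2 (−1.10) and Tbx22 (−1.40), all expressed in palatal mesenchyme, were lower. With equal cells per cluster 2 of 34 were called, both higher. The calls lost there were those of Dlx6 and Dlx1 (edgeR adjusted p = 0.449 and 0.755, ranges 3.2e-05 to 0.587 and 0.0109 to 0.759) and all 3 lower ones, Meox2, Osr2 and Tbx22 (edgeR adjusted p = 0.107, 0.0829 and 0.430, ranges 0.000278 to 0.520, 0.000596 to 0.583 and 0.0217 to 0.589). DESeq2 did not call Osr1, Dlx1 or Tbx22 (adjusted p = 0.0553, 0.0665 and 0.226, range for Osr1 0.000689 to 0.634). Without KO/KO 2, Dlx6 stood at 0.93 and Osr1 at 0.65. The list's median was 0.01, and turned to −0.11 without KO/KO 1 and −0.09 without KO/KO 2. Its mean was 0.09 while the set test pointed down. The list did not pass the set test (adjusted p = 0.641; adjusted p = 0.694 with an estimated correlation).

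**Figure D3:**
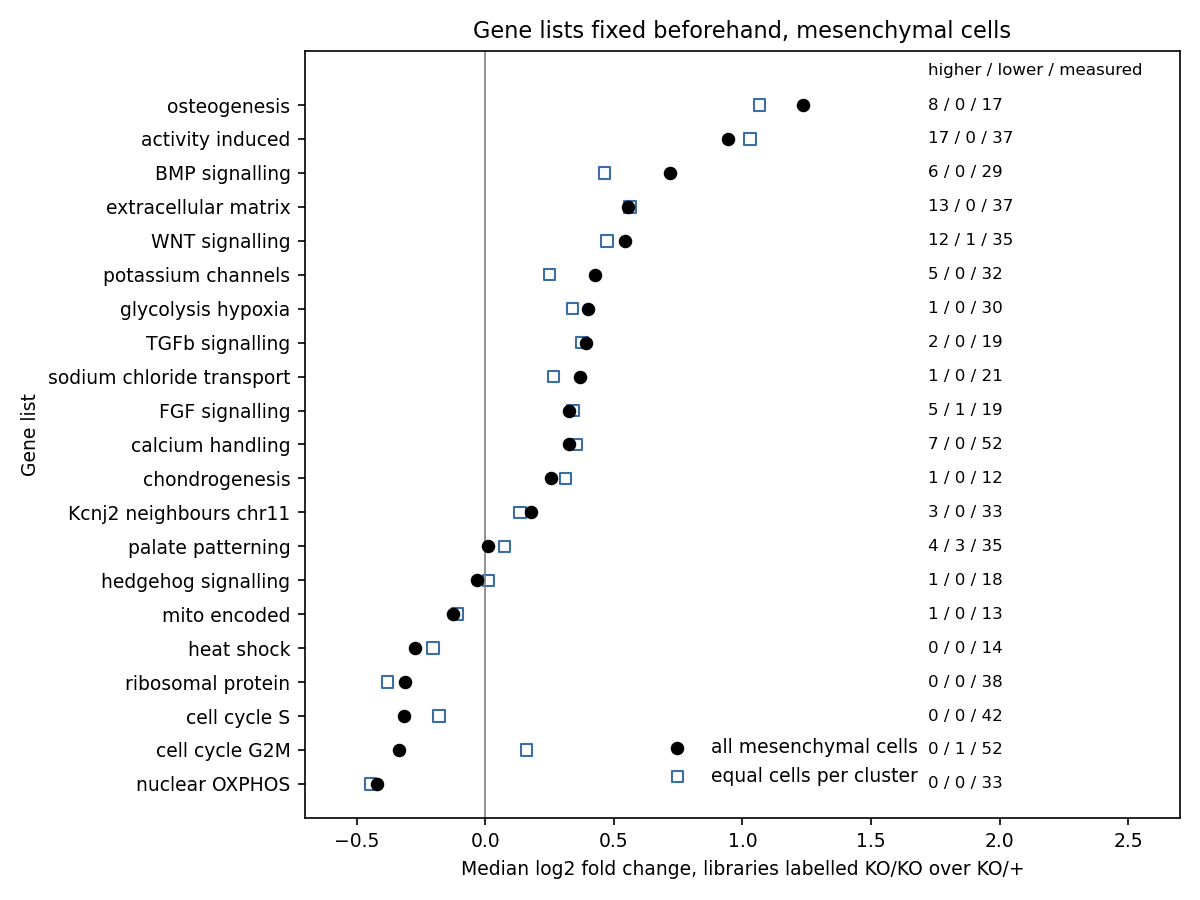
Median log2 fold change (horizontal axis) of each gene list other than the sex lists in mesenchymal cells (filled points) and with equal cells per cluster (open squares), with the numbers of members called higher, called lower and measured at the right. The osteogenesis and activity-induced lists had the highest medians, 1.24 and 0.94, and the medians of the G2/M and hedgehog lists changed sign with equal cells per cluster.

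Cell cycle genes had lower medians in mesenchymal cells of the libraries labelled KO/KO, with few single genes called. In the S phase list 0 of 42 members were called by edgeR, DESeq2 and limma-voom, with 12, 12 and 7 at an unadjusted p under 0.05 and 0 by edgeR adjusted over the list alone. Its median was −0.31, or −0.50 without KO/KO 1 and −0.16 without KO/KO 2. It was −0.18 with equal cells per cluster, −0.07 in shared clusters and −0.12 in G1 cells. In the G2/M list edgeR called 1 of 52, DESeq2 called 4 and limma-voom 1. The gene edgeR called lower was Cdc20, an activator of the anaphase-promoting complex (log2 −0.97, SE 0.27), also adjusted over the list alone, and this call was lost with equal cells per cluster (edgeR adjusted p = 0.578, range 0.00669 to 0.755). The median of the G2/M list was −0.34, or −0.56 without KO/KO 1 and −0.17 without KO/KO 2, and turned to 0.16 with equal cells per cluster and 0.25 in shared clusters. In G1 cells it was −0.44, with 6 members called lower and 0 higher. Cells were scored as G1 with the S and G2/M lists themselves, so values in G1 cells are no separate check of these lists. Both lists passed the set test (adjusted p = 1.0e-05 for S and 1.3e-06 for G2/M; adjusted p = 0.574 and 0.572 with an estimated correlation). Cells scored as G1 made up 68.9 ± 5.97% (SD, n = 2) of mesenchymal cells thinned to 5000 UMIs in the libraries labelled KO/KO and 55.1% (53.9 to 56.4) in the library labelled KO/+, against 66.7 ± 6.32% and 52.2% without thinning. Thinning left out 640, 171 and 287 mesenchymal cells of KO/KO 1, KO/KO 2 and KO/+.

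Few genes of the metabolic lists were called in mesenchymal cells. Nuclear genes of oxidative phosphorylation had 0 of 33 called and a median of −0.42 (−0.23 without KO/KO 1, −0.65 without KO/KO 2), and ribosomal protein genes 0 of 38 and −0.31 (−0.09 and −0.57); both counts were 0 adjusted over the list alone and by DESeq2 and limma-voom, with 1 and 0 members at an unadjusted p under 0.05 by edgeR, 6 and 1 by DESeq2 and 0 and 0 by limma-voom. The set test gave adjusted p = 1.0e-05 and 0.000426, and adjusted p = 0.634 and 0.668 with an estimated correlation. Glycolysis and hypoxia genes had 1 higher of 30, the lactate transporter Slc16a3 (log2 0.94), also adjusted over the list alone, lost with DESeq2 (adjusted p = 0.235, range 0.00294 to 0.619) and at 0.57 without KO/KO 2; the set test gave adjusted p = 0.0168, and adjusted p = 0.572 with an estimated correlation. Of 13 mitochondrially encoded genes mt-Nd6 alone was higher (1.13, and 0.54 without KO/KO 1), also adjusted over the list alone, and DESeq2 did not call it (adjusted p = 0.0729, range 0.00559 to 0.628); here the median was −0.12 and the mean 0.02, and the list did not pass (adjusted p = 0.549; adjusted p = 0.668 with an estimated correlation). Haemoglobin and other erythroid markers were lower in mesenchymal cells of the libraries labelled KO/KO, with 7 of 8 called and a median of −1.72, and in epithelial cells, with 6 of 6 called and a median of −2.24. Epithelial markers in mesenchymal cells had a median of −0.65, with 1 of 11 called lower, Krt14 (log2 −1.15, and −2.40 without KO/KO 1 and −0.49 without KO/KO 2). DESeq2 did not call Krt14 (adjusted p = 0.493, range 0.00714 to 0.709). Among neuron markers 1 of 8 was higher, Stmn2, and 2 were lower, Nefl and Tubb3; among macrophage markers 1 of 8 was higher, Mrc1, and among markers of other leukocytes 2 of 7 were lower, Coro1a and S100a9. Of the mesenchyme markers Col1a1 was higher and Meox2 and Osr2 were lower, of 10. With equal cells per cluster the calls of Tubb3, Mrc1, Coro1a, S100a9 and Col1a1 were lost (edgeR adjusted p = 0.159, 0.182, 0.0694, 0.192 and 0.0868, highest over the alternatives 0.578, 0.378, 0.397, 0.966 and 0.413). edgeR, DESeq2 and limma-voom called 0 of 4 periderm, 9 endothelium, 5 skeletal muscle, 5 glia and 3 melanocyte markers, with 1, 2, 2, 1 and 0 at an unadjusted p under 0.05 by edgeR.

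In epithelial cells, the homeobox genes Dlx1 and Dlx2 and the WNT ligands Wnt3, Wnt7b and Wnt10a were higher in the libraries labelled KO/KO. Fgf8 was lower. These sums compare unlike mixtures too. At doubled resolution an epithelium-like cluster led by Dsc3, Irx2 and Irx1 held 373, 91 and 144 cells. An unnamed cluster with Epcam in 97.6% of its cells, led by Dmrt2 and Fgf9, held 437, 76 and 588. No alternative with equal cells per cluster was run in epithelial cells. Dlx2, a homeobox gene of craniofacial patterning, had 34.5 and 44.3 CPM in KO/KO 1 and KO/KO 2 against 5.14 CPM (log2 2.93, SE 0.33), and Maf, a transcription factor, 31.1 and 25.7 against 4.46 CPM (2.68, SE 0.34). Fgf8, a signalling ligand of facial epithelium, had 2.60 and 1.94 against 12.8 CPM (−2.44, SE 0.41), Six2 11.1 and 9.29 against 32.3 CPM (−1.65, SE 0.28) and Mgp, matrix Gla protein, 37.7 and 32.5 against 97.8 CPM (−1.47, SE 0.26). Tmsb15b1 was higher here too (log2 5.41), and Tsix lower (−4.50). The chemokine Cxcl14 (4.31 and 76.2 against 2.73 CPM) and Hspa12b (1.86 and 29.0 against 0.991 CPM) were called higher, and Tpm3-rs7, a copy of Tpm3 with shared sequence, lower (2.15 and 33.7 against 50.4 CPM), yet each rested on 1 of the libraries labelled KO/KO: without KO/KO 2 the log2 values were 0.65 and 0.88, and Tpm3-rs7 went from −4.53 without KO/KO 2 to −0.58 without KO/KO 1. edgeR called 165 of 13210 genes, 104 higher and 61 lower, from 895, 193 and 898 cells; DESeq2 called 36, and of the genes named in this paragraph it kept Tmsb15b1, Dlx1, Dlx2, Wnt3, Maf, Mgp and Tsix.

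Epithelial WNT signalling genes had 4 higher of 29 in the libraries labelled KO/KO, or 6 higher and 2 lower adjusted over the list alone. They were the ligands Wnt3 (log2 3.72, SE 0.60), Wnt10a (2.01, SE 0.40) and Wnt7b (1.48, SE 0.31) and the receptor Fzd1 (1.15, SE 0.29), of which DESeq2 kept Wnt3. The WNT list did not pass the set test (adjusted p = 0.610; adjusted p = 0.862 with an estimated correlation). Palate patterning genes had 5 higher and 3 lower of 28, or 5 and 6 adjusted over the list alone, and DESeq2 called Dlx1 and Dlx2 alone. Dlx2, Dlx1 (3.55), Tfap2b (3.49, and 1.10 without KO/KO 2), Msx2 (2.47, and 1.51 without KO/KO 2) and Barx2 (1.18) were higher, and Barx1 (−1.06), Twist1 (−1.44) and Osr2 (−1.43) lower, with a median of −0.19 (−0.38 without KO/KO 1) and a mean of 0.10 (set test downward, adjusted p = 0.367; adjusted p = 0.862 with an estimated correlation). Without KO/KO 1, Twist1 stood at −2.79 and Osr2 at −2.17, or at −0.93 and −1.07 without KO/KO 2. Both are also mesenchyme markers, of which 2 of 9 were lower in these sums, 0 by DESeq2 with 2 at an unadjusted p under 0.05. The median of these markers was −0.35, which became −1.03 without KO/KO 1 and 0.03 without KO/KO 2. Activity-induced genes had 1 higher of 36, Nr4a1 (1.08), or 2 adjusted over the list alone, and a median of 0.22 that was −0.17 without KO/KO 1 and 0.42 without KO/KO 2. Nr4a1 was 0.44 without KO/KO 1 and was not called by DESeq2, with RLE size factors or without the count filter (adjusted p from 0.0616 to 1.00). The matrix list had 2 higher, Timp3 (2.44) and Has2 (2.18), and 1 lower, Mfap4 (−1.05), of 35, or 6 and 3 adjusted over the list alone. DESeq2 kept Timp3 and did not call Has2 or Mfap4 (adjusted p = 0.0566 and 1.00, lowest over the alternatives 1.8e-05 and 0.0148).

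Single members of other lists were called in epithelial cells. These were Msx2 in BMP signalling (1 of 27, or 2 adjusted over the list alone), Tgfb2 in TGF-beta signalling (log2 1.00, and 0.61 without KO/KO 1; 1 of 17, or 1), Fgf8 in FGF signalling (1 lower of 17, or 1), Runx2 in osteogenesis (1.11; 1 of 11, or 2 higher and 1 lower), Kcnh1 among potassium channels (2.61; 1 of 20, or 1) and Ano1 among sodium and chloride transport genes (−1.04; 1 lower of 19, or 1). Of these Kcnh1 alone kept its call under each alternative with a test. DESeq2 did not call Msx2, Fgf8, Runx2 or Ano1 (adjusted p = 1.00, 0.0750, 1.00 and 1.00, lowest over the alternatives 4.8e-10, 5.1e-07, 0.0405 and 0.0226), and the Tgfb2 call was lost under all 3 alternatives with a test (adjusted p from 0.0648 to 1.00). In the sex lists 4 of 4 Y-linked genes were higher and Xist was lower, with 2 lower of 7 adjusted over the list alone. edgeR called 0 members of the lists for heat shock, hedgehog signalling, chondrogenesis, calcium handling, S phase, G2/M, glycolysis and hypoxia, mitochondrially encoded genes, oxidative phosphorylation, ribosomal proteins and the Kcnj2 neighbours, also adjusted over each list alone. DESeq2 called 0 in each of these too, and the members at an unadjusted p under 0.05 by edgeR were 0, 0, 1, 4, 2, 7, 3, 1, 0, 0 and 2 in that order. limma's camera test passed 6 of 22 lists, all downward: FGF signalling (adjusted p = 0.00924), S phase (0.0111), G2/M (3.0e-05), oxidative phosphorylation (3.0e-05), ribosomal proteins (0.00134) and X inactivation (0.00134). With an estimated correlation each of these 6 had adjusted p = 0.862.

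In endothelial cells, summed from 86, 53 and 86 cells, genes typical of mesenchyme were lower in the libraries labelled KO/KO, as were single markers of other cell types. Barx1, a homeobox gene of oral mesenchyme, had 3.40 ± 0.27 CPM (SD, n = 2) against 49.3 CPM (log2 −3.83, SE 0.39), Gpc6, a glypican, 11.1 ± 0.81 against 95.4 CPM (−3.09, SE 0.33) and Osr2 2.41 ± 2.11 against 32.0 CPM (−3.58, SE 0.46). Tfap2b had 1 UMI over the libraries labelled KO/KO and 63 in the library labelled KO/+, for a ratio of 98.1 with a counting interval from 17.0 to 3934, and DESeq2 did not call it (adjusted p = 0.0795, range 2.0e-14 to 0.0795). As markers, 7 of 10 mesenchyme genes were lower, 2 by DESeq2 (median −1.77). In contrast 0 of 9 endothelium markers were called by edgeR or DESeq2, and 0 had an unadjusted p under 0.05 by either (median 0.11). A total of 13 of 23 patterning genes were lower, or 17 lower and 1 higher adjusted over the list alone, with 3 called by DESeq2. Of erythroid markers 4 were lower and 1 higher of 9, 3 by DESeq2, among them the embryonic globin genes Hba-x (−8.46, SE 0.46) and Hbb-y (−6.84, SE 0.41). The epithelium marker Krt14 (−2.95, SE 0.66; 1 lower of 3) and the pericyte marker Pdgfrb (−3.21, SE 0.83; 1 lower of 4) were lower too. DESeq2 called neither (adjusted p = 1.00 for both, lowest over the alternatives 8.4e-05 and 0.00172). Without KO/KO 1 or KO/KO 2, Krt14 stood at −4.92 or −1.83. Genes with higher levels included Tnfrsf11b, the decoy receptor osteoprotegerin (12.4 and 18.3 against 2.69 CPM), and the histone gene Hist1h2bn (2.29 and 34.1 against 2.09 CPM), and without KO/KO 2 the log2 value of Hist1h2bn was 0.12. Trim12a was at least 10.9-fold and Tmsb15b1 at least 9.21-fold higher against a floor of 3 counts in the library labelled KO/+. Tsix, at 0 in both libraries labelled KO/KO, was at least 158-fold lower against a floor of 3 counts over the group. edgeR called 108 of 10875 genes, 24 higher and 84 lower; DESeq2 called 13, none of the named higher genes among them. These cells had a median of 32447 UMIs, 2.50 times the median of their libraries. Doublets with mesenchymal cells, or RNA of mesenchymal cells in these sums, were not excluded.

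The genotype difference itself was tested between epithelial and mesenchymal cells with the library as a block. It differed for 622 of 15835 genes by edgeR, 151 with a higher and 471 with a lower effect in epithelial cells, and for 100 genes by DESeq2. The sums of both classes compare unlike mixtures of clusters, and no interaction with equal cells per cluster was run. Unequal mixtures were therefore not excluded as a source of these differences. Effects more positive in epithelium included Tubb3, a neuronal tubulin (difference of log2 fold changes 3.95, SE 0.35), Dlx2 (2.37, SE 0.23), the basal keratin gene Krt14 (1.53, SE 0.14) and Meis2 (1.29, SE 0.13), and DESeq2 called neither Krt14 nor Meis2 (adjusted p = 1.00 for both, ranges 1.0e-27 to 1.00 and 6.4e-23 to 1.00). Effects more negative in epithelium included Dkk2 (−4.29, SE 0.31), the matrix protein gene Smoc2 (−3.92, SE 0.17), Ptprz1, a receptor phosphatase (−3.42, SE 0.20), and Igfbp5 (−1.62, SE 0.11). Krt14 is an epithelium marker, and its lower mesenchymal level, given above, differed between the libraries labelled KO/KO. RNA of epithelial cells in the mesenchymal sums was not excluded as its source there.

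Summed over all cells, Smpd3 (log2 5.31, SE 0.36), Tnn (4.18, SE 0.34), Ptgfr (4.16, SE 0.34), Col12a1 (3.87, SE 0.31) and Spock1 (3.67, SE 0.31) were again higher in the libraries labelled KO/KO. Fbxo44 (−3.31, SE 0.46), Cited1 (−1.93, SE 0.30) and Tsix (−7.38, SE 0.47) were lower. The neuropeptide gene Vip had 108 UMIs and the homeobox gene Tlx2 60 UMIs in the library labelled KO/+ and 0 in both libraries labelled KO/KO. Both were thus at least 47.7-fold and 26.5-fold lower against a floor of 3 counts over the group. How many cells held these UMIs was not counted, so a few cells of the library labelled KO/+ could hold them all. edgeR called 91 of 16870 genes, 84 higher and 7 lower. The count was 317 with DESeq2, 57 with limma-voom, 320 with RLE size factors, 552 at equal depth, 580 over all deposited barcodes, and 0 by edgeR without the count filter, where 1081 genes had an unadjusted p under 0.05.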

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

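The 9 tests that weigh explanations in this part were chosen after the results they measure had been seen, while the interaction test was planned.

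The genotype difference was not the same in epithelium and mesenchyme for 622 genes, by the edgeR test of the difference itself, with the library as a block. DESeq2 called 100 of them. No interaction with equal cells per cluster was run, so unequal mixtures of clusters were not excluded as a source. Dkk2, for one, was the leading gene of cluster 0, which was nearly absent from KO/+. Of the named genes, those whose effect was more positive in epithelial cells were Tsix (difference of log2 fold changes 6.95), Tubb3 (3.95), Dlx2 (2.37), Krt14 (1.53) and Meis2 (1.29). Those whose effect was more negative were Dkk2 (−4.29), Smoc2 (−3.92), Ptprz1 (−3.42) and Igfbp5 (−1.62). For Krt14, an epithelium marker, RNA of epithelial cells in the mesenchymal sums was not excluded. Tsix, which lies antisense to Xist, had 5 and 3 UMIs in mesenchymal and 123 and 37 UMIs in epithelial cells of KO/KO 1 and KO/KO 2, against 14648 and 3035 in KO/+. Endothelium-like cells had a mean doublet score of 0.0626 against 0.0381 in mesenchymal cluster 0, and doublets of these cells with mesenchymal cells were not excluded.

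Mesenchymal clusters 0 and 7 held 35.4% and 43.3% of mesenchymal cells of KO/KO 1 and KO/KO 2 and 0.216% of those of KO/+. Depth is argued against as the cause, because the median UMI count of KO/+ lay between those of the other libraries and its share of 0.216% did not. Clusters set apart by the called genes alone are argued against too. Clustering without them still gave a cluster with 24.3% of the KO/KO cells on average. At halved resolution of the first clustering no cluster was nearly absent from KO/+ (0%). Genes that differed between the libraries without being called stayed in the clustering without the called genes, and no integration was used. A shift of whole libraries in such genes was therefore not excluded. The part of the palate taken from each embryo cannot be told apart from the genotype, since among the remaining mesenchymal cells cluster 4 took 24.4% in KO/+ and 9.26% and 13.3% in KO/KO, and each group's dissection coincided with its label. A difference tied to genotype, to sex or to anything else that set the 1 KO/+ embryo apart stays open and was not tested.

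In mesenchymal cells of the libraries labelled KO/KO, 17 of 37 activity-induced genes were called higher and 0 lower, 7 by DESeq2. Unequal numbers of cells per cluster are argued against, since the list's median was 1.03 with equal cells per cluster, at percentile 100 of random lists. The random lists leave out the correlation between members. With that correlation estimated the list did not pass camera's set test in all mesenchymal cells (adjusted p = 0.572). Hardly any list could pass that test on 1 residual degree of freedom, so it does not decide. A stress response that also raises heat-shock genes is argued against by the heat-shock median of −0.27 with no member called higher. This does not cover a stress response without heat-shock genes, which stays open. In endothelial cells of the same suspensions edgeR called 1 of 14 heat-shock genes, Hspa1b, lower in KO/KO (log2 −4.07, adjusted p = 6.5e-05). DESeq2 called 0 there, and the list's median was 0.05. Handling of each suspension cannot be told apart from genotype, since each embryo was handled on its own: the epithelial median was 0.22, and the mesenchymal medians were 0.49 without KO/KO 1 and 1.35 without KO/KO 2. Genotype, sex and anything else that set the 1 KO/+ embryo apart stay open and were not tested.

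Kcnj2 transcript was higher in mesenchymal cells of the libraries labelled KO/KO, against the direction of a lost transcript. Unequal cluster numbers are argued against, as in 6 of the 6 shared clusters the lower counting bounds of both KO/KO libraries lay above the upper bound of KO/+. An exchange of the KO/+ library with one of the others is argued against by 0 UMIs of the 4 Y-linked genes in it, although a swap with a sample not analysed here or an error in genotyping stays open. A transcript of the targeted allele that keeps its 3′ end would leave UMIs such as the 6071 seen in KO/KO mesenchymal cells, and this cannot be told apart from a normal transcript because 3′ counts do not show which part of the gene is deleted. Genotype and sex stay open and were not tested.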

How the results depend on the processing

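The alternatives with cluster 9, with shared clusters, with clustering without the called genes, for the nearly absent clusters at other resolutions, and for list medians other than without a replicate were chosen after the result was seen, and the others were planned. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Leaving out a replicate left 1 library against 1 with no residual degrees of freedom, so it gave fold changes and medians but no counts of calls; Kcnj2 in mesenchymal cells ranged from 1.26 to 1.27.

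The mesenchymal count of 844 fell to 487 with DESeq2 (474 of them shared with the first test), 340 with equal cells per cluster (327 shared), 374 in shared clusters (360 shared) and 6 over all deposited barcodes. With all barcodes a cluster of 1450, 1166 and 4 cells, led by the pericyte marker Kcnj8, stayed unnamed and out of the class, and the prior degrees of freedom that edgeR estimated went from infinite to 3.51. Kcnj2 was not called there (log2 1.31, edgeR adjusted p = 0.299, range over the alternatives with a test 4.5e-05 to 0.299). Why the other 3 settings called fewer genes was not tested. The other counts lay from 626 with limma-voom to 858 in G1 cells. In all cells the count of 91 became 317 with DESeq2, 57 with limma-voom, 320 with RLE size factors, 552 at equal depth, 580 over all deposited barcodes and 0 without the count filter by edgeR, where 1081 genes had an unadjusted p under 0.05. The edgeR counts went with prior degrees of freedom of 8.53 in the first test, 22.4 with RLE, 2.19 without the filter and infinite at equal depth and over all barcodes. With DESeq2 the epithelial count went from 165 to 36, the endothelial from 108 to 13 and the interaction from 622 to 100; the cause was not tested. Without the count filter and with RLE factors those of epithelium and endothelium stayed within 1.5 times, as did the interaction without the filter.

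With a correlation estimated per list, camera passed 0 of 22 lists in mesenchymal cells, where 17 had passed, and 0 in epithelial cells, where 6 had. The G2/M median turned from −0.34 to 0.16 with equal cells per cluster and 0.25 in shared clusters. Among single genes and list medians under the alternatives, 246 values lost a call and 23 gained one. The other values counted as unchanged were 2560, which is not a number of kept calls. They include genes called neither in the first test nor under the alternative, values without an adjusted p, and medians of lists that had not passed.

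Differences of shares (KO/KO mean minus KO/+, percentage points) also moved, and the cause was not tested. For mesenchymal cells 10.9 became 7.09 at halved and −0.721 at doubled resolution and −13.6 over all barcodes; for unnamed cells −6.93 became −3.59, 1.62 and 16.7. Epithelial cells went from −2.23 to 1.10 at doubled resolution, where a cluster of 437, 76 and 588 cells with Epcam in 97.6% of them stayed unnamed. Endothelium went from 0.177 to 0.0854 at halved and −0.102 at doubled resolution, and over all barcodes macrophages went from 0.0690 to 0.0278 and erythroid cells from −1.81 to −1.25. The glia difference of −0.149 has no counterpart at halved resolution, where no cluster was named glia-like and each library had 0 such cells. Nearly absent clusters held 39.4% of KO/KO mesenchymal cells, 0% at halved and 25.7% at doubled resolution and 24.3% without the called genes. The 25.7% leaves out an osteogenic-like cluster of 646, 600 and 14 cells, which lay just over the limit of 1%. Kcnj2 in KO/KO was 44.7 CPM, and 46.5 without TMM factors.

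Other splits were too few for a share under 0.05: of 3, the real one called 844 genes in mesenchymal cells and the highest other 4, against 91 and 6 in all cells, 165 and 21 in epithelial and 108 and 41 in endothelial cells. Endothelial sums rested on 86, 53 and 86 cells, which limits what these can show.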

Other observations

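The values in this part were chosen after they were seen, and no explanation is tested in it.

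In endothelial cells the list of palate patterning genes was not the sole list with lower values in the libraries labelled KO/KO. WNT signalling genes had 3 of 15 called lower, also adjusted over the list alone, and 0 by DESeq2 with 3 at an unadjusted p under 0.05, with a median of −1.22 (limma's camera test, adjusted p = 1.6e-09; adjusted p = 0.548 with an estimated correlation). Extracellular matrix genes had 6 of 30 called lower, or 7 adjusted over the list alone, and 0 by DESeq2 with 6 at an unadjusted p under 0.05, and a median of −0.32 (adjusted p = 8.4e-06; adjusted p = 0.548 with an estimated correlation). Hedgehog signalling genes had 0 of 10 called by edgeR and by DESeq2, with 5 and 1 at an unadjusted p under 0.05, 5 lower by edgeR adjusted over the list alone, and a median of −1.04 (adjusted p = 1.2e-06; adjusted p = 0.548 with an estimated correlation). The called matrix genes included the mesenchyme markers Postn, Col3a1 and Col1a2. In these cells edgeR called 7 of 10 mesenchyme markers lower and 0 of 9 endothelium markers. RNA of mesenchymal cells in the endothelial sums, or doublets with them, was not excluded as a source of the lower values. Unlike the lists above, the G2/M list had a positive median, 0.50 (0.60 without KO/KO 1 and 0.25 without KO/KO 2). edgeR and DESeq2 called 0 of 52, with 10 and 2 at an unadjusted p under 0.05. limma's camera test gave adjusted p = 3.2e-10, and adjusted p = 0.564 with an estimated correlation. In mesenchymal cells the G2/M median was −0.34, but 0.16 with equal cells per cluster and 0.25 in shared clusters. The difference between these classes was not tested.

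A total of 17 genes were called by edgeR in mesenchymal, epithelial and endothelial cells alike. Most were sex-linked or globin genes: Ddx3y, Eif2s3y, Kdm5d, Uty, Xist, Tsix, Erdr1, Hba-x, Hbb-y and Hbb-bt. Trim12a and Tmsb15b1, whose values are uncertain as given above, and Hist1h2bn were also among the 17. Of the remaining genes, Nr4a1 was higher (log2 3.44, 1.08 and 1.43, or 2.52, 0.44 and 0.73 without KO/KO 1), and DESeq2 called it in none of the 3 classes (adjusted p = 0.0890, 1.00 and 1.00, lowest over the alternatives 2.5e-22, 0.0616 and 0.00796). Dlk1 was lower (−1.50, −1.33 and −2.91), and DESeq2 called it in mesenchymal cells and not in epithelial or endothelial cells (adjusted p = 0.697 and 1.00, lowest over the alternatives 0.00113 and 0.000177). Osr2 had values of −1.10, −1.43 and −3.58, but its mesenchymal call was lost with equal cells per cluster (log2 −0.86, edgeR adjusted p = 0.0829, range 0.000596 to 0.583) and DESeq2 did not call it in epithelial cells (adjusted p = 1.00, lowest 0.0377).

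Among erythroid-like cells, those with mostly embryonic globin were 22 of 27 in KO/KO 1 (81.5%, exact binomial 95% interval 61.9 to 93.7), 19 of 29 in KO/KO 2 (65.5%, 45.7 to 82.1) and 73 of 203 in KO/+ (36.0%, 29.4 to 43.0). Summed over these cells, embryonic globin made up 54.2%, 40.3% and 52.7% of globin UMIs, with KO/+ between the libraries labelled KO/KO. Globin UMIs made up 0.020%, 0.0879% and 0.0898% of the UMIs of all other cells.

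Chromosome X had 541 genes tested in mesenchymal cells, with a median log2 fold change of 0.12 and 23 called higher and 4 lower. The autosomes had 15290, with a median of 0.03 and 612 called higher and 190 lower, and chromosome 11, which carries Kcnj2, had 1242 with a median of 0.01 and 32 called higher and 9 lower. Within single shared mesenchymal clusters edgeR called 379, 467, 162, 271, 329 and 302 genes in clusters 1, 2, 3, 4, 6 and 13.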
